A study of Mus musculus with 27 samples.

How the data were processed

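The data are Drop-seq libraries of mouse thymus: in Drop-seq, single cells are enclosed in droplets with barcoded beads, so that each transcript carries the barcode of its cell and a unique molecular identifier (UMI). Per the labels' protocols, thymic lobes of timed C57BL6/J embryos were taken apart with trypsin, red cells were lysed in some samples, and single cells negative for the dead-cell dye 7AAD were sorted. The E12.5 samples had no red cell lysis, and the organ cultures had another lysis reagent than the lobes taken directly from embryos. Libraries followed Drop-seq protocol version 3.1 and were sequenced on a NextSeq 500, per the labels' protocols. Per the submitters' processing notes, STAR 2.4.2, Picard 1.96 and SAMtools 1.3 were used with the mm10 genome build; their settings are not given in the sources used here.

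For each of the 27 libraries the authors deposited a table of whole-number UMI counts per gene and cell, and a second table of UMI counts per T-cell receptor segment and cell. The values were used as deposited counts, without further normalization by the authors. The gene tables used here list 20036 genes over 24279 cells, and the cell with the fewest genes has 1000. Mitochondrial genes, T-cell receptor genes and the chemokine gene Ccl21a are not analysed here from the gene tables. Libraries hold 1326309 to 5932042 UMIs and 276 to 1397 cells. Gene positions come from GENCODE M21, which describes the same assembly as mm10, and were matched by gene symbol.

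Groups were taken from the labels: 8 wild-type or reporter ages, the Rag1 knockout at E16.5, and control and retinoic acid organ cultures. The tests, comparisons, gene lists, markers and the rule for named genes were fixed before the data were examined. Choices made after seeing the data are named as such here and beside the values.

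Cells needed at least 500 genes, which all passed. In each library the 5% of cells with the highest doublet score from scrublet in scanpy 1.11.5 were removed, 1218 in all, which left 23061. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components and 15 nearest neighbours went into Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), which gave 22 clusters. Clusters were called "like" the cell type whose fixed markers gave the highest score. A marker was used if it reached 50 CPM in a cluster, and counted as detected with a UMI in 10% of cells. At least 3 markers were needed, and the 10 leading genes by fold held no more markers of another type. The scoring rule for names was settled after the clusters were seen. A first rule left 6 clusters with 6337 cells unnamed, another misnamed a cluster, and the adopted one was the last of 3. Effects of the first rule are given with the alternatives.

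T-lineage and epithelial cells were clustered again with 20 components into 15 and 12 subclusters. A subcluster took a state's name where its marker score was at least 0.5 and led the next by 0.3. Markers of that state also had to be among its 10 leading genes by fold. These rules were also set after seeing the data, as the last of 3 versions. They kept 7007 of 13031 T-lineage cells and 3477 of 5792 epithelial cells out of the named states. Unnamed T-lineage cells were 51.3% at E13.5, 36.5% at E14.5, 67.0% at E15.5, 46.0% at E16.5, 17.8% at E17.5, 12.8% at E18.5, 91.6% in the Rag1 knockout, 80.7% in control and 88.2% in retinoic acid cultures. Unnamed epithelial cells were 91.0% at E12.5, 90.7% at E13.5, 81.4% at E14.5, 77.2% at E15.5, 81.1% at E16.5, 81.7% in the knockout, 21.8% in control and 14.0% in retinoic acid cultures. State shares therefore describe the named part only. Epithelial states were not compared between the cultures, although they were compared between other groups with larger unnamed shares. T-lineage states were not compared at E12.5, and classes with fewer than 100 cells (parathyroid and endothelial) were not tested, both decided after seeing the data.

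Shares of cells were compared across days by Pearson and Spearman correlation with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Between 2 groups of libraries the mean difference was tested by a two-sided exact permutation test, whose smallest p is 0.1 for 2 against 3 or 3 against 3 libraries. Both were adjusted by the Benjamini-Hochberg method within each family. T-cell receptor counts were expressed per 10000 UMIs of the library, and segment classes with fewer than 100 counts were not tested, a limit set after seeing the counts. The highest level that a count of 0 allows was set at 3 counts, which covers counting error only.

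Cells are not replicates, so counts were summed per library and class, and a library entered a fit with at least 20 cells of the class. edgeR 4.0.16 (R 4.3.3) was run with TMM scaling, its filter on low counts and the quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Slopes are linear changes of log2 expression per day from E13.5 to E18.5. Fits of the Rag1 knockout took the spread from all groups from E13.5 to P0 that were not cultured, as fixed in advance, because the compared groups hold 2 and 3 libraries. Gene lists with at least 5 tested members were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, and again with an estimated correlation. With the estimated correlation 4 list calls hold for the slope in T-lineage cells, 6 for the epithelial slope, 1 for E13.5 against E12.5 in mesenchymal cells, and 1 and 2 for retinoic acid in T-lineage and mesenchymal cells; 0 hold in the other fits. DESeq2 1.42.0 was run as an alternative.

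The named genes follow a rule: per fit the 4 largest changes in each direction among genes that pass, average at least 50 CPM, mark no other class and, for group comparisons, do not overlap between libraries; up to 2 genes per list and direction with the smallest adjusted p; and genes named in advance for each class. Some genes that this rule picks are not reported here. CPM values, the count of a gene scaled to one common total for each class and library, were computed here from the deposited counts.

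Each fit was tested on simulated counts drawn from the means of the real genes, with 200 genes changed. Of 100 genes changed 4-fold over the range of a fit, 92 were recovered for the slope in T-lineage cells, 76 for the epithelial slope, 73 for the mesenchymal slope, 93 and 91 for E13.5 against E12.5 in epithelial and mesenchymal cells, 88 and 57 for the knockout in T-lineage and epithelial cells, and 94, 96 and 85 for retinoic acid in T-lineage, epithelial and mesenchymal cells. Unchanged genes were 4.29% of calls for the slope in T-lineage cells and 10.9% for E13.5 against E12.5 in epithelial cells, the lowest and highest share of these fits.

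Replicate numbers were checked for pairing by correlating deviations from group means. Control and retinoic acid cultures with the same number had correlations of 0.224 to 0.369, each above 0.1, the limit set for pairing. Control and retinoic acid cultures with different numbers had -0.240 to -0.0373, but deviations within a group sum to 0, so the 2 sets of values are not independent. Over all groups, libraries with different numbers reached 0.333, and 14.3% of their correlations were above 0.1. That 0.333 involves E17.5, a group of 2 libraries, where it mirrors a same-number value of -0.333. The values of the cultures go with pairing by number. They rest on 3 pairs and no label says so, so pairing is not established. No libraries of a group agreed within sampling noise. Alternatives covered size factors, the count filter, DESeq2, the clustering resolution, doublet removal, free RNA, cell filters, replicate blocks and leaving out each library. The free RNA of a library was estimated from markers of other classes, and the processed pseudogene share was added as a covariate after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.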

Results

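Single cells of the developing mouse thymus were profiled by Drop-seq, a droplet method that counts the messenger RNA of each cell by the 3' ends of transcripts and tags every molecule with a unique molecular identifier (UMI). The mice were C57BL6/J. Whole thymic lobes gave 3 libraries at E12.5 from Pax9VENUS embryos, 3 at E13.5, 2 at E14.5, 2 at E15.5, 3 at E16.5, 2 at E17.5, 2 at E18.5 and 2 at birth (P0). A further 2 libraries came from E16.5 embryos with the Rag1 gene knocked out. Rag1 and Rag2 form the enzyme that cuts the T-cell receptor genes, so that their segments can be joined. In fetal thymic organ culture, lobes taken at E13.5 were kept for 3 days with 1 µM retinoic acid (3 libraries) or in control medium (3 libraries).

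The 27 libraries held 24279 cells and 20036 genes. Libraries ranged from 276 to 1397 cells and from 1326309 to 5932042 UMIs, with a median of 2483.5 to 6786.5 UMIs per cell. The deepest library was replicate 3 at E13.5 and the shallowest replicate 2 at E18.5. After removal of 1218 cells with the highest doublet scores, 23061 cells remained. Levels are given as CPM, the UMI count of a gene scaled to one common total for every cell class and library, as mean ± SD over libraries, and log2 changes carry their standard error. The labels do not say that libraries of a group came from separate animals or litters, so p-values measure only the spread between these libraries.

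The first question was how the cell types of the thymus change over embryonic days. T-lineage-like cells made up 2.31 ± 1.34% of cells at E12.5 (n = 3), 18.9 ± 7.32% at E13.5 (n = 3), 57.0 ± 7.00% at E15.5 (n = 2), 87.0 ± 2.84% at E16.5 (n = 3) and 94.9 ± 0.723% at E18.5 (n = 2). Thymic epithelial-like cells, the stroma that attracts and instructs thymocytes, went from 49.5 ± 0.804% at E12.5 and 40.6 ± 4.94% at E13.5 to 5.24 ± 2.13% at E16.5 and 2.63 ± 1.01% at E18.5. As a separate class, early T progenitor-like cells, the most immature thymic lymphocytes, were 25.2 ± 5.68% at E13.5, 14.4 ± 0.348% at E14.5 and 1.15 ± 0.268% at E18.5. The same markers also named a state within the T-lineage class. That state held 47.3 ± 6.08% of T-lineage-like cells at E13.5 and 62.2 ± 10.2% at E14.5, when the T-lineage class was 46.4 ± 2.61% of cells. The share of the separate class therefore does not date a peak of early progenitors. Mesenchymal-like cells went from 21.7 ± 3.50% at E12.5 to 8.79 ± 3.72% at E13.5 and 0.492% at E16.5. Parathyroid-like cells, which share the third pharyngeal pouch origin of the thymus, were 3.30 ± 0.130% of cells at E12.5 and 0.0509% at E13.5. Within the T lineage, cells resembling the double-positive stage, at which CD4 and CD8 are both on the surface, were 6.54 ± 2.05% at E15.5, 44.7 ± 6.76% at E16.5, 77.0 ± 1.5% at E17.5 and 82.1 ± 1.97% at E18.5.

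Over the 14 libraries from E13.5 to E18.5, the share of T-lineage-like cells rose with day (Pearson r = 0.952, Spearman rho = 0.969). Shares of epithelial (r = -0.934, rho = -0.931), early T progenitor (r = -0.913, rho = -0.938) and mesenchymal cells (r = -0.878, rho = -0.931) fell. Each of these 4 had p = 1e-05, the smallest that 100000 resamples of a two-sided permutation test can give, and an adjusted p of 1.5e-05 over the 6 classes tested. Myeloid-like cells (r = -0.850, permutation p = 0.00013) and innate lymphoid and NK-like cells (r = -0.847, permutation p = 0.00027) fell as well. The E18.5 and the E13.5 libraries lie equally far from the median day. Without those of E18.5, r was 0.976 for T-lineage, -0.957 for epithelial, -0.936 for early T progenitor and -0.894 for mesenchymal cells, and without those of E13.5 it was 0.917, -0.874, -0.909 and -0.880. The double-positive share rose within the T lineage (r = 0.944, rho = 0.964), and cells with genes of T-cell receptor (TCR) signalling and maturation rose too (r = 0.911, rho = 0.878). The shares are parts of one total of sorted viable cells, so one class gains where another loses. At Leiden resolution 0.5 the correlation of innate lymphoid and NK-like cells with day was 0.705 and that of the TCR signalling share -0.0204.

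**Figure D1:**
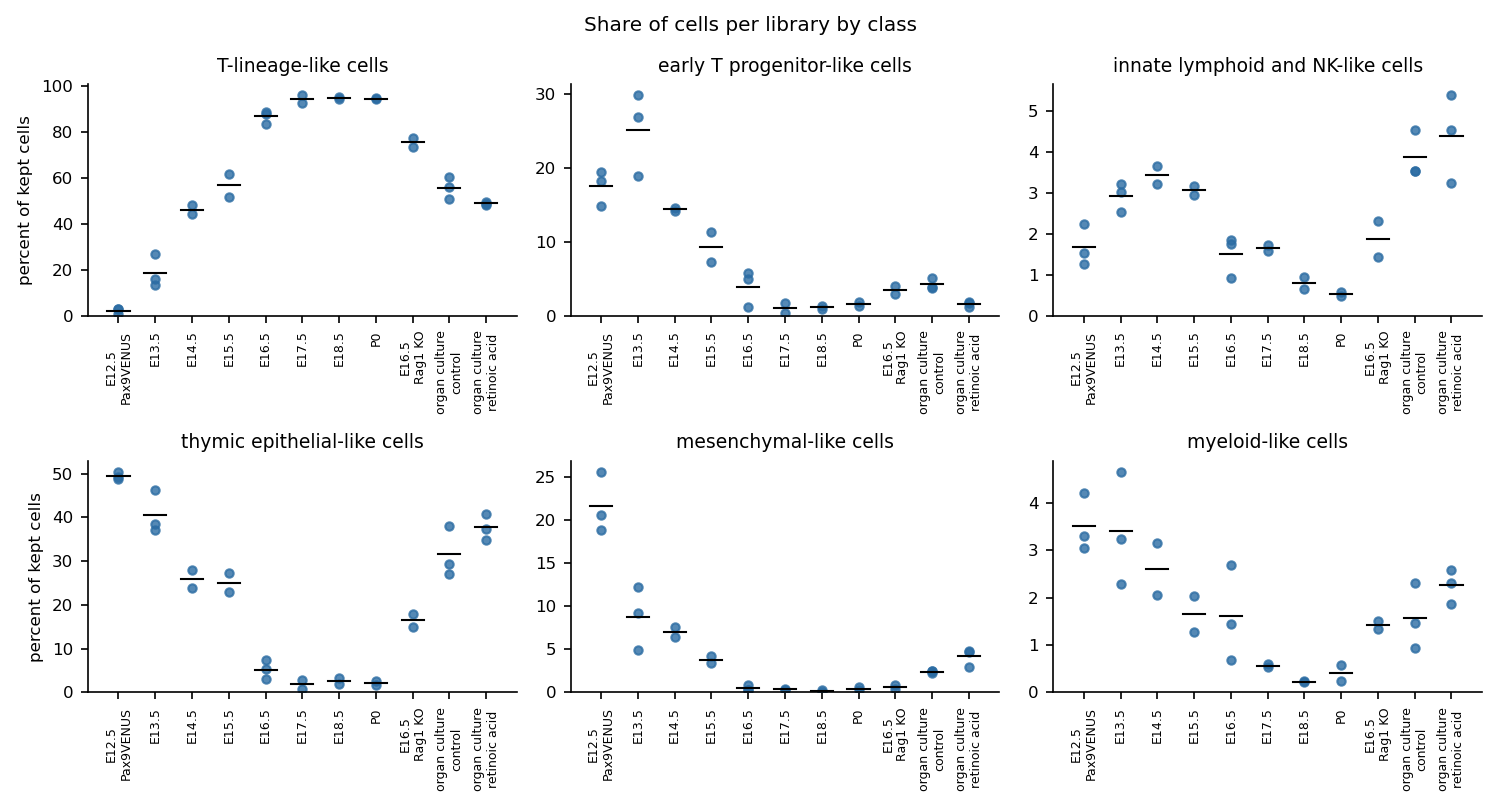
Percent of kept cells per library (points) in 6 cell classes, for each group on the horizontal axis; lines mark the group mean. T-lineage-like cells average 2.31% at E12.5 and 94.9% at E18.5, while thymic epithelial-like cells go from 49.5% to 2.63%.

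T-cell receptor segments were counted in a separate table per library. Constant and some other segments can be transcribed before rearrangement, so these counts alone do not date it. Gamma variable segments were counted at 0.0512 ± 0.0464 per 10000 UMIs at E13.5 (n = 3), 0.562 ± 0.152 at E15.5 (n = 2) and 1.74 ± 0.254 at E18.5 (n = 2), and the delta constant segment went from 0.10 ± 0.0231 to 3.67 ± 0.207. Beta variable segments stood at 0.0607 ± 0.00315 at E13.5 and 0.199 ± 0.149 at E16.5, then at 1.19 ± 0.141 at E17.5 and 5.12 ± 0.136 at E18.5. The alpha constant segment, of the last locus to rearrange, was at 0.0187 ± 0.0223 at E16.5, 0.342 ± 0.125 at E17.5, 3.43 ± 0.399 at E18.5 and 4.28 ± 0.755 at P0. Gamma variable (r = 0.888, rho = 0.942), delta constant (r = 0.817, rho = 0.922), beta variable (r = 0.736, rho = 0.929) and alpha constant counts (r = 0.674, rho = 0.743) rose with day over 14 libraries by a two-sided permutation test (12 tests in the family). The gamma constant segments had r = 0.199 (permutation p = 0.492), but with only 14 counts at E13.5 and 7 at E18.5, beside 88 and 492 gamma variable counts. So few counts do not show that their level stayed flat. Beta constant segments had 0 and 2 counts at these days, beside 100 and 1440 beta variable counts. Counts are per UMI of the whole library, so they also follow the growing share of T-lineage cells. They were not limited to the cells that pass the cell filters.

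**Figure D2:**
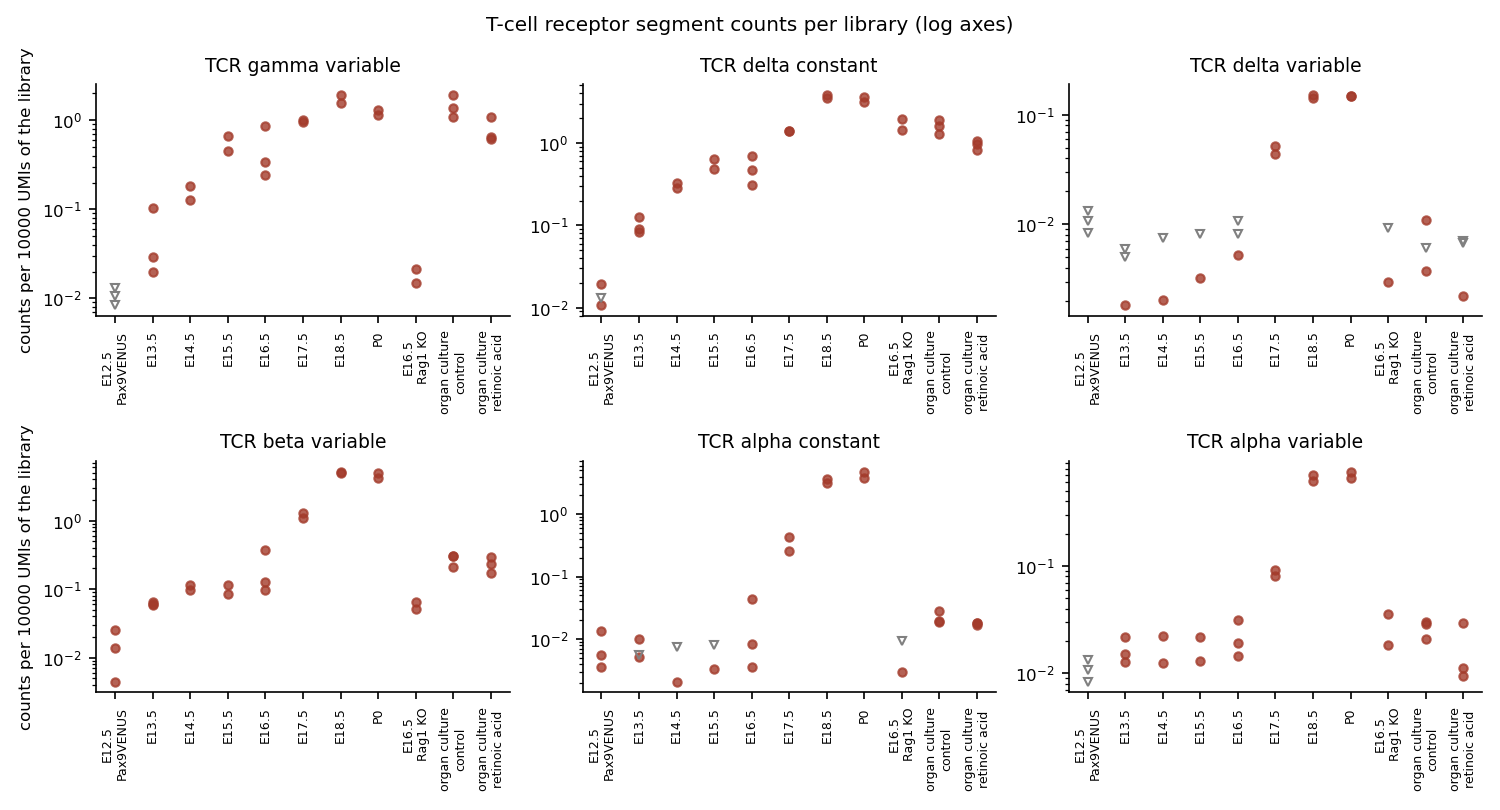
T-cell receptor segment counts per 10000 UMIs of the library on log axes, one point per library, for 6 segment classes across groups; open triangles mark libraries with 0 counts, drawn at the level that 3 counts would give. Beta variable counts average 0.199 at E16.5 and 5.12 at E18.5, and gamma variable counts average 0.0181 in the Rag1 knockout against 0.483 at E16.5.

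Within T-lineage-like cells, the co-receptor genes gained most per day from E13.5 to E18.5 among the genes reported here. Cd8a (chromosome 6, 71373427 to 71379173, protein coding), a chain of the CD8 co-receptor, rose by 2.12 ± 0.18 log2 per day, from 1.32 ± 0.0587 CPM at E13.5 to 145 ± 31.0 at E16.5 and 736 ± 36.5 at E18.5. Its partner Cd8b1 rose by 2.11 ± 0.14 and Cd4, the co-receptor for MHC class II, by 2.04 ± 0.18 per day. Cd4 had 0 UMIs at E13.5 and reached 92.0 ± 2.58 CPM at E18.5. Ccr9, the receptor for the thymic chemokine Ccl25, rose by 1.10 ± 0.11, the co-stimulatory receptor Cd28 by 1.08 ± 0.11 and the transcription factor Tcf7 by 0.50 ± 0.03. Ifitm1 (chromosome 7, 140967221 to 140969825), an interferon-inducible membrane protein, had the steepest fall among them (-1.93 ± 0.12 per day, 6831 ± 1556 CPM at E13.5 and 12.1 ± 11.1 at E18.5). The neuropeptide galanin gene Gal (-1.88 ± 0.10), the granzyme gene Gzmb (-1.88 ± 0.12) and the chromatin protein gene Hmga2 (-1.72 ± 0.13) fell in the same libraries.

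Of 11 measured genes of the double-positive stage, 9 rose and 1 fell, Rag2, and these counts were the same adjusted over the list alone (adjusted p = 1.26e-13 by camera with the preset correlation, adjusted p = 0.00289 with an estimated correlation). All 7 measured innate lymphoid and NK genes fell, among them the adaptor genes Fcer1g (-1.38 ± 0.07) and Tyrobp (-1.51 ± 0.09); camera gave adjusted p = 5.06e-18 with the preset correlation and adjusted p = 0.00151 with an estimated correlation, and 7 fell adjusted over the list alone. 7 of 8 early T progenitor genes fell, such as the stem cell factor receptor gene Kit (-0.71 ± 0.05) and the transcription factor gene Hhex (-0.98 ± 0.06), with 7 lower and 1 higher adjusted over the list alone (adjusted p = 1.1e-14 by camera with the preset correlation, adjusted p = 0.004 with an estimated correlation). 46 of 52 G2/M genes rose, for example the mitotic kinesin gene Kif11 (0.36 ± 0.03), and 48 rose adjusted over the list alone. For that list camera gave adjusted p = 3.09e-17 with the preset correlation and adjusted p = 0.108 with an estimated correlation. 27 of 42 S phase genes rose and 2 fell, with 28 and 2 adjusted over the list alone (adjusted p = 4.83e-09 by camera with the preset correlation, adjusted p = 0.0736 with an estimated correlation). Rag1 rose by 0.23 ± 0.04 and Rag2 fell (-0.11 ± 0.03), a call lost without E13.5 replicate 3. Il2ra, the interleukin 2 receptor chain of double-negative thymocytes, stood at 380.4 ± 54.8 CPM at E13.5, 852 ± 53.2 at E15.5 and 193 ± 30.9 at E18.5, and Ptcra, the pre-TCR alpha chain, at 198 ± 125, 601 ± 1.16 and 196 ± 15.1.

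In all, 1837 genes rose and 1864 fell of 9791 tested over 14 libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted p was 1.12e-08 for Cd8a, 1.79e-10 for Ifitm1 and 0.746 for Ptcra by the same test. Epithelial transcripts moved with day in these cells, with Krt8 at -1.0 ± 0.13 and Krt18 at -0.77 ± 0.09 log2 per day. The days occupy different clusters of the class. Clusters 17 and 5 held 36.3% and 35.4% of its cells at E13.5, and clusters 6 and 0 held 37.5% and 37.3% at E18.5. Cluster 17 was named by a narrow lead, with a score of 2.86 for T-lineage and 2.75 for innate lymphoid and NK markers. It held 0 of these cells at E18.5. At Leiden resolution 2 a cluster led by Gzmb and Gal was named innate lymphoid and NK. How far the falls of Gal, Gzmb, Cd163l1 and the innate lymphoid and NK list follow this class boundary was not tested. With cell classes named by the first rule tried, 2362 genes passed.

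In thymic epithelial-like cells, genes of antigen presentation and of the interferon response rose from E13.5 to E17.5. H2-K1 (chromosome 17, 33996017 to 34000347), an MHC class I heavy chain, rose by 0.78 ± 0.05 log2 per day, from 123 ± 16 CPM at E13.5 (n = 3) to 624 ± 8.19 at E16.5 (n = 3) and 1117 in the single E17.5 library. The class II chain H2-Aa rose by 0.85 ± 0.08 (294 ± 175 to 1824 ± 142 CPM at E16.5). The interferon-induced genes Ifi27l2a (2.08 ± 0.17), Isg20 (1.59 ± 0.10) and Isg15 (1.09 ± 0.12) rose more steeply. Tbata (chromosome 10, 61171954 to 61188841), a gene of cortical epithelium, rose by 1.38 ± 0.09 from 140.4 ± 66.9 to 2081 ± 512 CPM at E16.5. Prss16, the thymus-specific serine protease, rose by 0.51 ± 0.06, Psmb11, the catalytic subunit of the thymoproteasome, by 0.42 ± 0.06, and the chemokine gene Ccl25 by 0.27 ± 0.06. Foxn1, the master transcription factor of thymic epithelium, had a slope of 0.15 ± 0.06 (adjusted p = 0.0566 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Igf2 (-1.13 ± 0.13), its imprinted neighbour H19 (-1.02 ± 0.09) and Hmga2 (-0.93 ± 0.11) fell.

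All 10 MHC class I genes and all 8 class II genes tested rose, over all genes and adjusted over the list alone. For class I camera gave adjusted p = 4.09e-25 with the preset correlation and adjusted p = 0.00631 with an estimated correlation. Class II gave adjusted p = 2.1e-20 by camera with the preset correlation, adjusted p = 0.0106 with an estimated correlation. 13 of 14 interferon genes rose by both counts, over all genes and adjusted over the list alone (adjusted p = 3.79e-17 by camera with the preset correlation, adjusted p = 0.0188 with an estimated correlation). Reads of near-identical MHC paralogs cannot be told apart with certainty. Of 12 cortical genes 9 rose, or 10 adjusted over the list alone, including the protease gene Ctsl (0.61 ± 0.06); camera gave adjusted p = 2.68e-15 with the preset correlation and adjusted p = 0.00631 with an estimated correlation. Cell cycle genes fell: 37 of 42 S phase genes, such as the replication licensing inhibitor gene Gmnn (-0.71 ± 0.07), fell by both counts, over all genes and adjusted over the list alone (adjusted p = 6.29e-28 by camera with the preset correlation, adjusted p = 0.0237 with an estimated correlation). 41 of 52 G2/M genes, such as Birc5 (-0.74 ± 0.10), which encodes the mitotic protein survivin, fell over all genes and 46 adjusted over the list alone. For G2/M camera gave adjusted p = 2.65e-28 with the preset correlation and adjusted p = 0.0859 with an estimated correlation. Medullary genes moved both ways, with 9 higher and 4 lower of 13 by both counts, over all genes and adjusted over the list alone, for example the basal keratin gene Krt5 (-0.37 ± 0.08) and the receptor gene Cd40 (0.60 ± 0.10); camera gave adjusted p = 0.0232 with the preset correlation and adjusted p = 0.209 with an estimated correlation. 7 of 11 T-lineage markers rose in the same cells, also adjusted over the list alone, among them Il2ra (0.84 ± 0.13); camera gave adjusted p = 0.000353 with the preset correlation and adjusted p = 0.209 with an estimated correlation.

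By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1383 genes rose and 1338 fell of 9636 tested over 11 libraries, with adjusted p = 1.8e-10 for H2-K1 and 3.75e-07 for Prss16. E17.5 enters with 1 library and E18.5 with none, since the others held fewer than 20 epithelial cells. Cluster 1 held 85.5% of the epithelial cells at E13.5 and cluster 7 78.3% at E16.5.

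**Figure D3:**
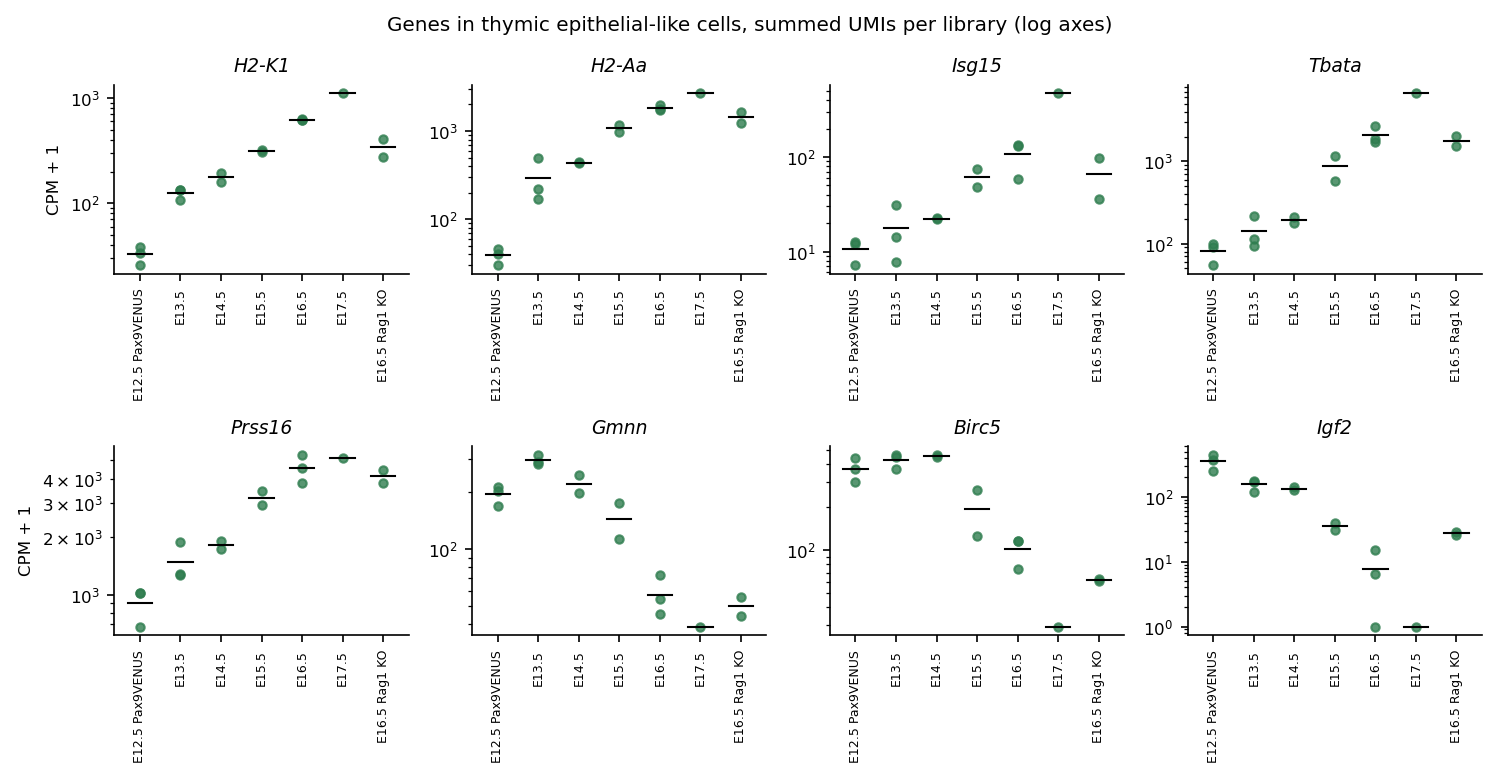
CPM + 1 on log axes for 8 genes in thymic epithelial-like cells, one point per library with at least 20 such cells, and lines at group means. H2-K1 averages 31.7 CPM at E12.5, 123 at E13.5 and 624 at E16.5, while Gmnn goes from 295 at E13.5 to 56.4 at E16.5.

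Mesenchymal-like cells allowed a slope from E13.5 to E15.5 only (7 libraries). Fn1 (chromosome 1, 71585520 to 71653200), the gene of the matrix protein fibronectin, rose by 1.13 ± 0.15 log2 per day from 157 ± 41.7 CPM at E13.5 (n = 3) to 746 ± 250.2 at E15.5 (n = 2). The basement membrane collagen gene Col4a1 rose by 0.91 ± 0.13, Col1a1 by 0.48 ± 0.12 (not called on leaving out any of 3 libraries) and Cspg4, a proteoglycan of mural cells, by 1.56 ± 0.25. Aldh1a2 (chromosome 9, 71215789 to 71296243), which makes retinoic acid, fell by 0.97 ± 0.19 per day from 339 ± 76.8 to 103 ± 33.7 CPM. Of 28 matrix genes 13 rose and 2, Lum and Mfap2, fell, with 16 and 2 adjusted over the list alone; camera gave adjusted p = 1.05e-06 with the preset correlation and adjusted p = 0.303 with an estimated correlation. The ribosomal precursor Rn45s rose by 1.99 ± 0.26, and over all cells of a library it averaged 165 CPM at E13.5 and 1016 at E15.5. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 310 genes higher and 228 lower of 3664, with adjusted p = 0.000571 for Fn1 and 0.00522 for Aldh1a2. DESeq2 called 166 higher and 186 lower, and without the filter on low counts 197 were higher and 504 lower, so the balance of directions is not stable. The total was 195 with replicate numbers as a block, 948 without doublet removal, 1102 with E12.5 added and, in a setting added after seeing the data, 249 with at least 1500 genes per cell. Leaving out E13.5 replicate 1, 2 or 3 left 269, 196 or 261 genes, and cluster 11 held 99.3% of these cells at E13.5 but 63.0% at E15.5. Cluster 19 held 37.0% at E15.5, and its score was 5.52 for mesenchymal and 5.34 for mural markers. Whether the slope of Cspg4 follows this change of clusters was not tested.

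E12.5 was set against E13.5 apart from the other days, because the E12.5 embryos carried the Pax9VENUS reporter and their samples had no red cell lysis, so day, genotype and handling cannot be separated. In epithelial-like cells H2-Aa was higher at E13.5 by 2.95 ± 0.34 log2 (37.8 ± 8.05 against 294 ± 175 CPM, n = 3 each), its chaperone Cd74 by 2.88 ± 0.42 and H2-K1 by 1.94 ± 0.17. Prss16 (0.70 ± 0.17), Ctsl (0.98 ± 0.14) and Pax9, a transcription factor of the pharyngeal pouch (0.49 ± 0.12), were higher at E13.5 too, with the call of Pax9 lost on leaving out any of 5 and that of Prss16 any of 2 of the 6 libraries. Igfbp5 (chromosome 1, 72857932 to 72874884), which binds insulin-like growth factors, was lower, with a log2 change of -3.13 ± 0.32 (578 ± 281 against 65.6 ± 33.7 CPM), as were the transcription factor gene Sox11 (-2.59 ± 0.29) and the claudin gene Cldn6 (-1.27 ± 0.19). Foxn1 differed by -0.18 ± 0.12 and Ccl25 by 0.03 ± 0.14, within the spread of the libraries. 7 of 10 MHC class I and 6 of 7 class II genes were higher (9 and 7 adjusted over the list alone). For class I camera gave adjusted p = 2.59e-18 with the preset correlation and adjusted p = 0.165 with an estimated correlation. Class II gave adjusted p = 5.53e-18 by camera with the preset correlation, adjusted p = 0.165 with an estimated correlation. Some mesenchymal markers were lower beside these, 4 of 15 over all genes and 7 adjusted over the list alone, for example Mfap4 (-1.89 ± 0.23). For that list camera gave adjusted p = 0.000393 with the preset correlation and adjusted p = 0.165 with an estimated correlation.

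In mesenchymal-like cells the small matrix proteoglycan gene Dcn (chromosome 10, 97479609 to 97518143) was higher at E13.5 by 2.58 ± 0.26 log2 (334 ± 136 against 1985 ± 899 CPM, n = 3 each), its relative Lum by 1.49 ± 0.20 and Fgf10, a growth factor for thymic epithelium, by 1.01 ± 0.25, a call lost on leaving out any of 4 libraries. Tgfbi (chromosome 13, 56609523 to 56639562), a secreted matrix protein, was lower, with a log2 change of -4.01 ± 0.46 (152 ± 47.4 against 9.67 ± 8.42), and the signalling genes Wnt5a (-2.33 ± 0.43) and Bmp4 (-1.3 ± 0.20) were lower. 7 of 29 matrix genes were higher and 1 lower, or 12 and 1 adjusted over the list alone (adjusted p = 8.15e-09 by camera with the preset correlation, adjusted p = 0.0325 with an estimated correlation). Of 16 immediate early and heat shock genes, which respond to stress and handling, 5 were higher and 1 lower, or 10 and 2 adjusted over the list alone, including Jun (1.35 ± 0.25) and Junb (1.46 ± 0.28), whose calls were each lost without 1 of the E13.5 libraries; camera gave adjusted p = 1.42e-06 with the preset correlation and adjusted p = 0.288 with an estimated correlation. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 338 genes were higher and 453 lower of 10344 in epithelial-like cells, and 108 and 80 of 6074 in mesenchymal-like cells, with adjusted p = 9.06e-05 for H2-Aa and 1.49e-06 for Dcn. With all groups sharing the spread 491 were higher and 405 lower in epithelial-like cells. DESeq2 called 478 in epithelial-like and 80 in mesenchymal-like cells, and without the filter on low counts 1339 and 312 passed. The mesenchymal count was 286 with replicate numbers as a block and, added after seeing the data, 67 with at least 1500 genes per cell. The epithelial count was 511 without E12.5 replicate 1, 384 without E12.5 replicate 2 and 469 without E13.5 replicate 2, and the mesenchymal count 95 without E12.5 replicate 2, 86 without E13.5 replicate 1 and 87 without E13.5 replicate 3. T-lineage-like cells were 2.31% at E12.5 and 18.9% at E13.5, and the mesenchymal share differed by -12.9 percentage points (exact permutation p = 0.1 for each, the smallest that 3 against 3 libraries can give, adjusted p = 0.15 over 6 classes). The T-lineage difference of 16.6 points was 5.49 at Leiden resolution 0.5 and 4.70 with the first rule for naming classes.

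The Rag1 knockout asks what the thymus looks like when receptor genes cannot be rearranged. Rag1 itself (chromosome 2, 101638282 to 101649501) was still counted, at 366 and 340.0 CPM in the T-lineage-like cells of knockout replicates 1 and 2 against 527 ± 8.25 CPM in the wild type at E16.5 (n = 3), a change of -0.62 ± 0.14 log2 that was not called without knockout replicate 2. The libraries count the 3' end of transcripts, which can lie outside the deleted part, so this checks nothing about the label. Variable segments bear on it more closely: those of gamma had 12 counts in the knockout and 524 in the wild type (0.0181 ± 0.00461 against 0.483 ± 0.337 per 10000 UMIs, exact permutation p = 0.2, adjusted p = 0.8). Alpha variable segments had 18 and 23 counts and were not lower in the knockout (0.0270 ± 0.0122 against 0.0216 ± 0.00871). Alpha or delta variable segments had 2 and 6 counts, and delta variable segments 1 and 2. Beta variable segments had 38 and 216 counts (0.0573 ± 0.00965 against 0.199 ± 0.149, exact permutation p = 0.3, adjusted p = 0.9), beta joining segments 26 and 27, and the delta constant segment 1127 and 525 (1.70 ± 0.368 against 0.492 ± 0.196, exact permutation p = 0.1, adjusted p = 0.6 over 12 classes). That difference of 1.21 was 0.425 with only the cells that pass the cell filters and 1.78 per 10000 UMIs of T-lineage cells. The counts above were not limited to cells that pass the filters, so they are not levels of the kept cells alone. With 2 libraries against 3, the smallest exact p is 0.1. Wild-type libraries ranged from 0.0974 to 0.370 for beta variable segments. Leaving out single libraries put knockout minus wild type at -0.192 to -0.0556 for that class.

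T-lineage-like cells of the knockout had fewer transcripts of later thymocyte stages. Cd8a was lower, with a log2 change of -5.97 ± 0.29 (2.34 ± 0.948 CPM, n = 2, against 145 ± 31.0, n = 3). So were Cd8b1 (-2.68 ± 0.24), Cd4 (-2.91 ± 0.57), the adhesion gene Cd2 (-3.59 ± 0.30), Cd28 (-2.92 ± 0.26) and Cd5 (-2.56 ± 0.28), a damper of TCR signals. Id3 (chromosome 4, 136143497 to 136145755), a TCR-induced inhibitor of E proteins, had 3 UMIs in the knockout and 109 ± 33 CPM in the wild type. H19 (chromosome 7, 142575529 to 142578143), an imprinted non-coding RNA, was higher by 1.98 ± 0.13 (7869 ± 743 against 1948 ± 156 CPM), Igf2 by 1.87 ± 0.20, Il2ra by 1.02 ± 0.14, Rag2 by 1.01 ± 0.13 and the Ets-family gene Erg by 1.38 ± 0.18. Of 12 genes of TCR signalling and maturation 7 were lower, or 9 adjusted over the list alone (adjusted p = 7.28e-08 by camera with the preset correlation, adjusted p = 0.0962 with an estimated correlation). 7 of 12 double-positive genes were lower and 1 higher, with the same counts adjusted over the list alone (adjusted p = 7.28e-08 by camera with the preset correlation, adjusted p = 0.0962 with an estimated correlation). 8 of 10 genes of double-negative stages 2 and 3 were higher, or 8 with 1 lower adjusted over the list alone; camera gave adjusted p = 3.05e-05 with the preset correlation and adjusted p = 0.0962 with an estimated correlation. The double-positive-like share was 0.280 ± 0.0472% of T-lineage-like cells in the knockout and 44.7 ± 6.76% in the wild type, and T-lineage-like cells were 75.7 ± 2.77% and 87.0 ± 2.84% of all cells (exact permutation p = 0.1 for each, adjusted p = 0.2 and 0.3). 5 of 13 epithelial markers were higher in these T-lineage-like cells, also adjusted over the list alone, such as Krt18 (1.36 ± 0.26), beside an epithelial share of 16 ± 2.18% against 5.24 ± 2.13%; camera gave adjusted p = 0.00223 with the preset correlation and adjusted p = 0.313 with an estimated correlation.

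EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1018 genes higher and 1038 lower of 10608 in T-lineage-like cells, with adjusted p = 1.39e-12 for Cd8a, 6.96e-10 for H19 and 0.00357 for Rag1. Transcripts of 82 processed pseudogenes also separated the groups over all cells, at 0.0481 ± 0.0107% of UMIs in the knockout (n = 2) and 0.156 ± 0.0278% in the wild type (n = 3). With that share as a covariate, added after seeing the data, 15 genes passed, 2 higher and 13 lower, while 1271 had an unadjusted p under 0.05; Cd8a was at -7.04 and H19 at 2.03 log2, both past the threshold, and Ptcra went from 0.85 ± 0.24 to -0.62. Il2ra was then at 0.64, Rag2 at 0.48, Erg at 0.53, Igf2 at 1.27 and Krt18 at 0.46, all smaller and no longer called. Cd8b1 (-3.35), Cd4 (-5.01), Cd5 (-3.77) and Rag1 (-1.29) lost their calls with larger changes than before. Both knockout libraries had the lowest shares of the 18 libraries in this fit, but the share also differed between days, at 0.0664% at E14.5 and 0.172% at E18.5, so what the covariate removes is not settled. Without knockout replicate 1 or 2 the count was 827 or 879, and DESeq2 called 1277. Clusters 2 and 4 held 48.2% and 37.2% of the T-lineage-like cells in the knockout, and cluster 0 held 0.276%, against 27.2% in the wild type.

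Thymic epithelial-like cells of the knockout differed in 4 of 11065 genes. Dsp (chromosome 13, 38151294 to 38198577), the desmosomal protein desmoplakin, was higher by 1.06 ± 0.20 log2 (2116 ± 136 CPM, n = 2, against 1051 ± 244, n = 3), and Rn45s by 1.39 ± 0.25. Ifi27l2a (chromosome 12, 103442167 to 103443680) was lower, with a log2 change of -2.37 ± 0.45 (35.8 ± 27.0 against 168 ± 115). The fourth, the pseudogene Rps19-ps3, was named after its value was seen, and its log2 change was -4.11 ± 0.38. Adjusted p was 0.0381 for Dsp and 0.0381 for Ifi27l2a by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The calls of Dsp and Ifi27l2a were each lost on leaving out any of 5 libraries and that of Rn45s on any of 3, with Ifi27l2a at up to -1.39 log2. With the processed pseudogene share as a covariate none of these 3 was called, though the changes were larger (Dsp 1.39, Ifi27l2a -6.32 and Rn45s 2.62; adjusted p = 0.599, 0.103 and 0.269 by the same test). Foxn1 (0.17 ± 0.20), Psmb11 (0.24 ± 0.21), Prss16 (-0.11 ± 0.20), Ccl25 (0.20 ± 0.20), Krt5 (-0.19 ± 0.30) and Aire (0.37 ± 0.77), the regulator of tissue antigens in the medulla, did not pass. Of 10 MHC class I genes 0 passed over all genes and 2 were lower adjusted over the list alone, with a median of -0.36; camera gave adjusted p = 0.00106 with the preset correlation and adjusted p = 0.634 with an estimated correlation. Counts in this comparison were unstable, from 1 to 19 on leaving out a library, 93 with DESeq2, 82 without the filter on low counts and 14 with replicate numbers as a block, while TMM called 2 higher and 2 lower and RLE size factors 2 higher and 6 lower. In a simulation of this comparison 57 of 100 genes changed 4-fold and 24 of 100 changed 2-fold were recovered.

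The organ cultures ask how added retinoic acid, a vitamin A derivative that acts through nuclear receptors, changes the fetal thymus. In thymic epithelial-like cells, some but not all known retinoid targets were higher after 3 days. Dhrs3 (chromosome 4, 144892827 to 144928209), a retinal reductase that lowers retinoic acid supply, was higher by 3.34 ± 0.16 log2 (325 ± 43.8 CPM against 32.0 ± 6.66, n = 3 each), and the retinoic acid hydroxylase genes Cyp26b1 and Cyp26a1 by 1.85 ± 0.16 and 2.16 ± 0.61. The retinol transporter gene Stra6 was higher by 1.38 ± 0.35; the call of Cyp26a1 was lost on leaving out any of 4 and that of Stra6 any of 3 of the 6 libraries. Rarb, a retinoic acid receptor, had 3 UMIs in controls and 151 with retinoic acid (33.1 ± 3.14 CPM). Cdx1, also among the named genes, was lower, but its call was lost without control replicate 1 or 2 or any single retinoic acid library. In those fits it was at -2.35 to -1.25 log2. The cytokeratin genes Krt14 (-3.01 ± 0.19; chromosome 11, 100203162 to 100207548), Krt17 (-1.46 ± 0.11) and Krt5 (-0.96 ± 0.12) of basal and medullary epithelium were lower, Krt5 at 514 ± 79.4 against 998 ± 74.8 CPM. The steepest other differences among the genes reported here were Plekhb1 (4.73 ± 0.17), Apba2 (3.70 ± 0.19), the lipase gene Mgll (-3.31 ± 0.25) and Anxa2 (-2.68 ± 0.16). Ccl25 (0.54 ± 0.11) and the endocytic receptor gene Ly75 (0.59 ± 0.10) were higher, whereas Foxn1 (0.25 ± 0.11), Psmb11 (0.03 ± 0.09) and Prss16 (-0.05 ± 0.09) did not pass.

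Of 16 retinoic acid genes 7 were higher and 1 lower over all genes, or 8 and 2 adjusted over the list alone (adjusted p = 5.49e-09 by camera with the preset correlation, adjusted p = 0.0518 with an estimated correlation). 5 of 12 medullary genes were lower and 1 higher, or 6 and 1 adjusted over the list alone; camera gave adjusted p = 3.1e-05 with the preset correlation and adjusted p = 0.274 with an estimated correlation. The higher one was the tight junction gene Cldn4 (2.0 ± 0.36). 4 of 12 cortical genes were higher, or 6 adjusted over the list alone (adjusted p = 0.0172 by camera with the preset correlation, adjusted p = 0.445 with an estimated correlation). 6 of 19 immediate early and heat shock genes were lower and 1 higher, also adjusted over the list alone, for example Fos (-0.91 ± 0.17); camera gave adjusted p = 0.0063 with the preset correlation and adjusted p = 0.504 with an estimated correlation. EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 781 genes higher and 634 lower of 10246, with adjusted p = 2.52e-08 for Dhrs3 and 0.000145 for Krt5. DESeq2 called 789, and the count was 925 without control replicate 1, 835 without retinoic acid replicate 1 and 879 without retinoic acid replicate 3. Cluster 7 held 52.7% of these cells in controls and 4.75% with retinoic acid, and cluster 9 held 20% and 72.1%.

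Retinoid genes were also higher in the mesenchymal-like cells of treated cultures. Dhrs3 had 2 UMIs in controls (9.30 ± 8.47 CPM) and 373 ± 80.4 CPM with retinoic acid, and Rarb 3 UMIs and 134 ± 19.9 CPM, the latter not called without retinoic acid replicate 3. Mgp (chromosome 6, 136872435 to 136875823), the calcification inhibitor matrix Gla protein, was lower, with a log2 change of -3.29 ± 0.29 (108 ± 31.7 CPM against 1046 ± 238, n = 3 each). The genes of elastin, Eln (-3.07 ± 0.46), of biglycan, Bgn (-1.92 ± 0.29), and of a fibrillar collagen, Col3a1 (-0.90 ± 0.18), were lower too. 4 of 7 retinoic acid genes were higher, or 6 adjusted over the list alone (adjusted p = 2e-16 by camera with the preset correlation, adjusted p = 0.0183 with an estimated correlation). 8 of 31 matrix genes were lower, or 10 adjusted over the list alone (adjusted p = 5.27e-10 by camera with the preset correlation, adjusted p = 0.0183 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 35 genes were higher and 30 lower of 2204, with adjusted p = 1.35e-06 for Mgp. With replicate numbers as a block 112 genes passed, without the filter on low counts 115, and with DESeq2 33. Cluster 19 held 92.9% of these cells in controls and 90.5% with retinoic acid. Its score was 5.52 for mesenchymal and 5.34 for mural markers, so by markers most of these cells were close to mural cells. At E13.5 cluster 11 held 99.3% of the class instead.

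In T-lineage-like cells of the cultures Gal (chromosome 19, 3409915 to 3414544) was higher with retinoic acid by 4.39 ± 0.34 log2 (103 ± 40.8 CPM against 4.89 ± 1.85, n = 3 each), the stress-response gene Osgin1 by 3.92 ± 0.26 and the immediate early transcription factor gene Egr1 (chromosome 18, 34859823 to 34864984) by 2.82 ± 0.15. The granzyme genes Gzma (0.98 ± 0.10) and Gzmb (1.24 ± 0.23), Il2ra (0.55 ± 0.09) and Dhrs3 (1.20 ± 0.22) were higher. Dntt, which adds untemplated bases at receptor junctions, was lower, with a log2 change of -1.84 ± 0.20 (16 ± 5.11 against 57.4 ± 4.63 CPM), as were Cd28 (-0.70 ± 0.12) and Rag2 (-0.48 ± 0.12), the last not called on leaving out any of 5 of the 6 libraries. Rag1 (-0.16 ± 0.11), Ptcra (0.29 ± 0.11) and Cd8a (0.32 ± 0.38) did not pass. 3 of 42 S phase genes were lower over all genes and 15 adjusted over the list alone, for example the nucleotide synthesis gene Rrm2 (-0.50 ± 0.10), not called on leaving out any of 3 libraries; camera gave adjusted p = 1.41e-08 with the preset correlation and adjusted p = 0.0432 with an estimated correlation. 7 of 52 G2/M genes were lower, or 16 adjusted over the list alone; camera gave adjusted p = 5.77e-11 with the preset correlation and adjusted p = 0.28 with an estimated correlation. 3 of 10 double-negative 2 and 3 genes were higher, or 6 adjusted over the list alone, and 3 of 11 double-positive genes were lower by both counts, over all genes and adjusted over the list alone. For the former camera gave adjusted p = 4.58e-05 with the preset correlation and adjusted p = 0.0712 with an estimated correlation. The latter gave adjusted p = 1.96e-05 by camera with the preset correlation, adjusted p = 0.17 with an estimated correlation. 5 of 15 immediate early and heat shock genes were higher, or 8 with 1 lower adjusted over the list alone; camera gave adjusted p = 4.7e-08 with the preset correlation and adjusted p = 0.147 with an estimated correlation.

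EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 184 genes higher and 100 lower of 9810 in T-lineage-like cells, with adjusted p = 5.27e-08 for Egr1 and 9.28e-05 for Dntt. The count was 709 with replicate numbers as a block, 666 without the filter on low counts and 122 with the first rule for naming classes, and 146, 156, 161 or 175 without control replicate 1, control replicate 3, retinoic acid replicate 1 or retinoic acid replicate 3. Cluster 8 held 31.4% of these cells in controls and 46.5% with retinoic acid. T-lineage-like cells were 55.8 ± 4.72% of the control and 49.0 ± 0.586% of the treated cultures, early T progenitor-like cells 4.28 ± 0.731% and 1.62 ± 0.390%, mesenchymal-like cells 2.43 ± 0.125% and 4.18 ± 1.06%, and within the T lineage the gamma-delta-like share was 1.48% and 0.200%. Each of these had exact permutation p = 0.1, the smallest for 3 against 3 libraries, with adjusted p = 0.2 over the classes and 0.1 over the T-lineage states. At Leiden resolution 0.5 the T-lineage difference went from -6.82 to -2.89 percentage points and the early T progenitor difference from -2.65 to -4.77. The gamma-delta-like difference turned at Leiden resolution 2, to 0.0221 percentage points higher with retinoic acid. Epithelial-like cells were 31.5 ± 5.82% and 37.7 ± 2.92% (exact permutation p = 0.3, adjusted p = 0.36). These tests ignore replicate numbers, and pairing by number is not established. Between cultures with the same number the epithelial share was higher with retinoic acid each time (40.7% against 38.1%, 34.9% against 27.1% and 37.4% against 29.3%).

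**Figure D4:**
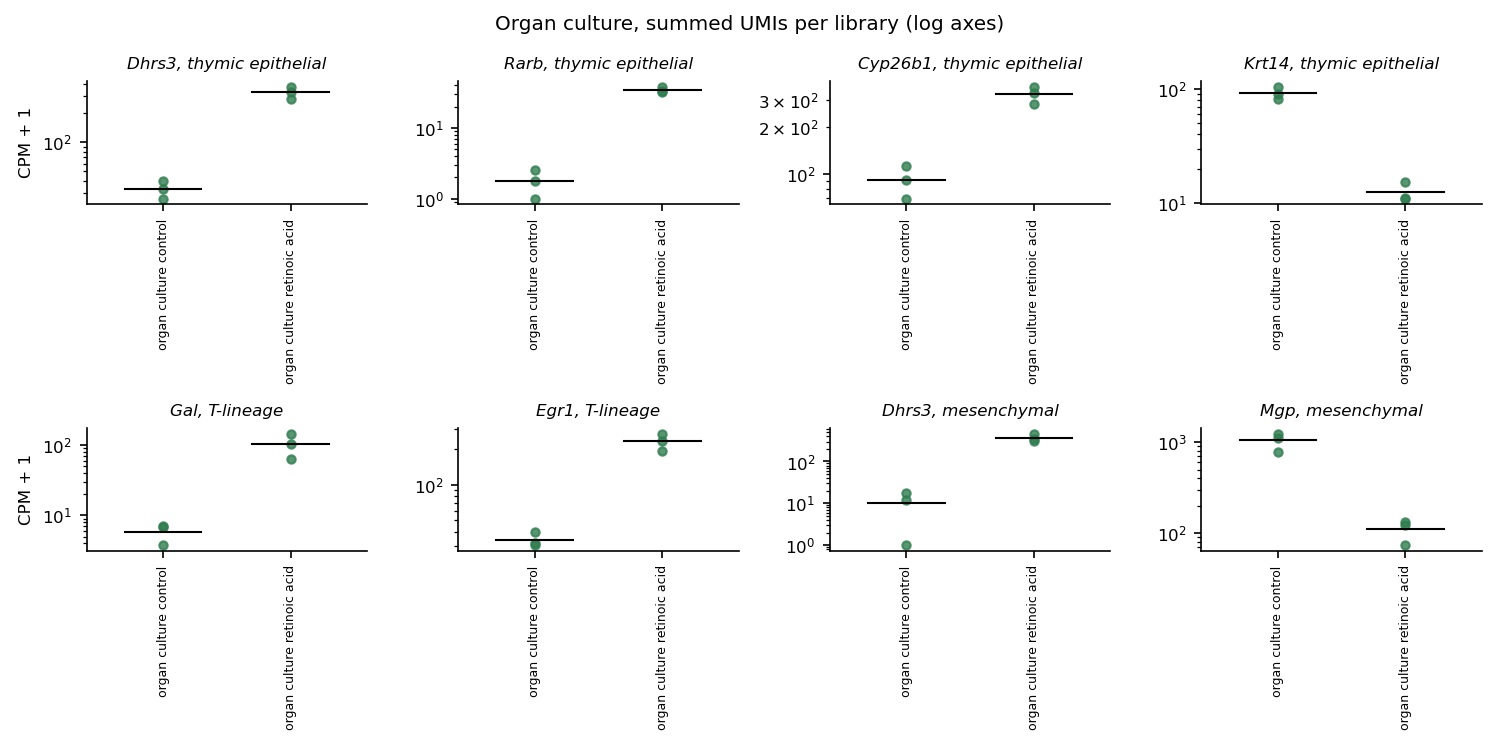
CPM + 1 on log axes for 8 genes in control and retinoic acid organ cultures, one point per library (n = 3 per group) and lines at group means, with the cell class in each title. Dhrs3 averages 32.0 and 325 CPM in epithelial-like cells, and Krt14 91.4 and 11.3.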

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

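The counts over other splits of the libraries were chosen only after the results were seen; the tests of free RNA, doublets and handling were written down before they were run, on patterns picked after the fits were seen.

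Genes of DNA replication and mitosis changed with day in opposite directions in epithelial and T-lineage cells by tests with the preset correlation. In a joint fit over the 11 libraries that hold both classes, the median slope of 42 S phase genes was lower in epithelial than in T-lineage cells by -0.60 log2 per day (adjusted p = 3.68e-29 by camera with the preset correlation, adjusted p = 0.0490 with an estimated correlation). For 52 G2/M genes the difference was -0.65 log2 per day (adjusted p = 1.05e-30, and adjusted p = 0.0800 with an estimated correlation). By single genes, 1108 had a higher and 1762 a lower slope in epithelial cells, of 12156 tested with edgeR. These lists drew attention because each passed in both cell types, in opposite directions, and the difference itself passed, all with the preset correlation. With an estimated correlation S phase did not pass in T-lineage cells (adjusted p = 0.0736) and G2/M in neither (adjusted p = 0.108 in T-lineage and 0.0859 in epithelial cells). The differences of MHC class I and class II genes passed as well (adjusted p = 0.0490 for each with an estimated correlation), but those lists did not pass in T-lineage cells or were not tested there.

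Immediate early and heat shock genes, such as Egr1 and Fos, responded differently to retinoic acid in the same cultures. The median difference of 19 genes, epithelial minus T-lineage change, was -0.97 log2 (adjusted p = 2.13e-07 by camera with the preset correlation, adjusted p = 0.188 with an estimated correlation). Over all genes the response was higher in epithelial cells for 231 and lower for 344 of 11805 tested with edgeR over 6 libraries.

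T-lineage markers such as Il2ra and Satb1 rose with day in epithelial cells, and thymocyte RNA from the medium or whole thymocytes are candidate sources. The median slope of the 11 tested markers was 0.593 log2 per day. After free RNA of the library was subtracted it was 0.172 over the 4 markers still tested (95% bootstrap interval -0.336 to 1.12). Without the 20% of cells with the highest doublet scores it was 0.291 over 6 markers (-0.0578 to 0.759). Both intervals, from draws of list members, reach below and well above 0. Both medians also cover fewer markers than the first, so the drop mixes a change of genes with the correction. At Leiden resolution 2 an unnamed subcluster of 193 epithelial cells over all groups, scored highest for medullary markers, had Il2ra among its 10 leading genes by fold, beside Ccl19 and Ubd. That bears on Il2ra only, not on the other markers. Free RNA and doublets thus both stay open, and a change of the epithelial cells with age stays open, untested.

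Immediate early and heat shock genes such as Jun and Junb were higher at E13.5 than at E12.5 in mesenchymal cells. If handling of the samples, which differed in red cell lysis, were the cause, other classes would share it, and in early T progenitor cells the median change of the list was 0.144 log2 (95% bootstrap interval -0.0733 to 0.551). Subtracting free RNA left the median in epithelial cells at 0.413, from 0.412 before (interval -0.106 to 0.785). That value comes from another class, so it does not speak for free RNA in mesenchymal cells. Neither value decides, so handling and free RNA cannot be told apart from age and the reporter genotype, which differ between the same libraries.

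Epithelial markers such as Krt18 and Cdh1 were higher in T-lineage cells of the Rag1 knockout, where epithelial cells are a larger part of the sample. The median change of 13 markers was 0.616 log2. Without the 20% of cells with the highest doublet scores it was 0.684 over 12 of them (95% bootstrap interval 0.437 to 1.21), so it did not fall. The interval comes from draws of list members and leaves out the spread between libraries, so captured pairs of cells stay open. With free RNA subtracted the median was 0.596 over the 5 markers still tested, with an interval of -2.64 to 1.3, so free RNA stays open. A difference in the knockout thymocytes themselves may also account for it and was not tested.

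Other splits of the same 6 libraries into groups of 3 were fitted for the comparisons of E13.5 with E12.5 and of the cultures. In each fit 1 of the 10 splits, the real one, gave as many genes. The real split gave 791 genes in epithelial and 188 in mesenchymal cells for E13.5 against E12.5, and the highest of the others gave 0 in both. For retinoic acid the real split gave 284 genes in T-lineage, 1415 in epithelial and 65 in mesenchymal cells, and the highest of the others 0, 1 and 0. Among splits of the cultures that also part all 3 pairs of numbers, the others gave 0 genes each. With 10 splits the share cannot fall under 0.1, so chance cannot be excluded by this count.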

How the results depend on the processing

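Settings chosen only after the results were seen are cells with at least 1500 genes, removal of the highest 20% of doublet scores, the first rule for naming classes, the processed pseudogene share as a covariate, P0 as the day after E18.5 for the states, summed alleles of TCR segments and, for gene list tests only, subtraction of free RNA and the replicate block. Of 450 values under another setting, 376 kept their direction, side of the threshold or size, 24 moved, 9 reversed, 15 became stronger and 26 weaker. On leaving out 1 library, 626 of 657 did so, 4 moved, 1 reversed, 5 became stronger and 21 weaker. For the changes below the cause was not tested, except where fewer cells, genes or libraries entered by construction.

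Among shares over days, innate lymphoid and NK-like cells had r = 0.705 at Leiden resolution 0.5, where the share of TCR signalling and maturation had r = -0.0204 and the medullary share r = -0.421. At resolution 2 the medullary share had r = 0.769 and the gamma-delta share r = -0.537, which was -0.422 without doublet removal and 0.562 with P0 entered as the day after E18.5. Knockout minus wild type at E16.5, in percentage points, was -2.49 for innate lymphoid and NK-like cells at resolution 0.5 and 1.14 at resolution 2, 0.823 for mesenchymal cells without doublet removal and 13.7 for epithelial cells with at least 1500 genes. Of the states, TCR signalling and maturation was at -0.146 at resolution 0.5 and -4.31 with at least 1500 genes, gamma-delta at -0.0436 at resolution 2, and cortical epithelium at 4.05 and 7.33 at resolutions 0.5 and 2 and -1.52 with at least 1500 genes. Retinoic acid minus control at resolution 0.5 was -2.89 for T-lineage, -4.77 for early T progenitor and -1.28 for innate lymphoid and NK-like cells and 0.277 for TCR signalling and maturation; gamma-delta was at 0.0221 at resolution 2 and -0.820 with at least 1500 genes. E13.5 minus E12.5 at resolution 0.5 was 5.49 for T-lineage (4.70 with the first naming rule), 18.1 for early T progenitor and 1.93 for innate lymphoid and NK-like cells (6.57 at resolution 2), and cortical epithelium was at 1.19 and 5.95 at resolutions 0.5 and 2.

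Per 10000 UMIs of T-lineage cells the gamma constant segments, which had few counts, had r = -0.598 with day. Knockout minus wild type was then 1.78 for delta constant and 0.0337 for delta joining segments. With only the cells that pass the cell filters these were 0.425 and 0.0127.

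With DESeq2 the genes called were 352 for the mesenchymal slope, 478 and 80 for E13.5 against E12.5 in epithelial and mesenchymal cells, 1277 and 93 for the knockout in T-lineage and epithelial cells, and 789 and 33 for retinoic acid in epithelial and mesenchymal cells. DESeq2 put the median log2 change of all genes for the knockout in epithelial cells at -0.26, against 0.02 with edgeR. Without the filter on low counts there were 1339 and 312 for E13.5 against E12.5 in epithelial and mesenchymal cells, 82 for the knockout in epithelial cells, and 666 and 115 for retinoic acid in T-lineage and mesenchymal cells. Directions shifted too: the mesenchymal slope had 197 genes higher and 504 lower without that filter, and retinoic acid in mesenchymal cells 74 and 41. With all groups sharing the spread E13.5 against E12.5 in epithelial cells had 491 higher and 405 lower, and retinoic acid in T-lineage cells 201 and 167. The first naming rule gave 2362 for the slope in T-lineage cells, with Blk at -0.122 and Sox13 at -0.0722, and 122 for retinoic acid there, 92 higher and 30 lower. The mesenchymal slope had 948 genes without doublet removal, 249 with at least 1500 genes per cell, where Sele was at -0.64, and 1102 with E12.5 added, where Lum was at 0.12. E13.5 against E12.5 in mesenchymal cells had 67 genes with at least 1500 genes per cell. For the knockout, RLE size factors gave 8 epithelial genes, removal of the highest 20% of doublet scores 2, and a fit of only the 5 libraries compared 1. With the processed pseudogene share as a covariate 15 T-lineage genes and 2 epithelial genes passed, and Ptcra was at -0.62. Of the named genes called in those fits, H19, Id3, Cd8a, Cd2, Cd28 and Cd6 kept their call with the covariate and 16 lost it, as did Ptcra on reversing; genes without a call, such as Dntt and Aire, stayed without one, some with the other sign.

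With replicate numbers as a block, retinoic acid called 709 genes in T-lineage and 112 in mesenchymal cells, and it moved no other count there by over 1.5 times. Over all fits 271 named genes, called or not, stayed on the same side of the threshold under the block, 3 gained a call and 2 lost it. Pairing by number is not established for the cultures, and for the other comparisons it is not shown. There the correlation of deviations was -0.190 to 0.229 for E12.5 and E13.5 and -0.327 and -0.0856 for E16.5 and the knockout. Some days did correlate, such as E14.5 and E15.5 at 0.284, while over all same-number pairs the median was 0.0110, so pairing over days stays open. The block gave 195 genes for the mesenchymal slope, 286 for E13.5 against E12.5 in mesenchymal cells, and 14 genes and 1 list call for the knockout in epithelial cells.

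List calls with an estimated correlation were 4, 6 and 0 for the slopes in T-lineage, epithelial and mesenchymal cells, 0 and 1 for E13.5 against E12.5 in epithelial and mesenchymal cells, 0 and 0 for the knockout, and 1, 0 and 2 for retinoic acid in T-lineage, epithelial and mesenchymal cells.

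Leaving out 1 library at a time gave 196 to 511 genes for the mesenchymal slope, 384 to 685 and 86 to 172 for E13.5 against E12.5 in epithelial and mesenchymal cells, 827 to 2239 and 1 to 19 for the knockout in T-lineage and epithelial cells, and 146 to 401 and 835 to 1177 for retinoic acid in T-lineage and epithelial cells. The knockout difference was -0.000978 to 0.0196 for gamma constant segments and 0.159 to 0.648 points for the gamma-delta share, whose correlation with day was -0.000307 to 0.422, and the medullary share had r of 0.236 to 0.762. Among named genes, calls of Rag1, Ptcra and Pdgfa in knockout T-lineage cells, of Dsp, Ifi27l2a and Rn45s in knockout epithelium, of Prss16, Psmb11, Pax9 and Crabp1 in epithelium and Fgf10, Jun and Junb in mesenchyme at E13.5 against E12.5, of Cyp26a1 and Stra6 in treated epithelium, of Rarb in treated mesenchyme, of Rag2, Rrm2, Nrarp and Lfng in treated T-lineage cells, of Rag2 in the T-lineage slope and of Col1a1 in the mesenchymal slope were among those lost without some library. Junb was at 0.91 without E13.5 replicate 3.

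Cells with at least 500 or 1000 genes are all cells, so those settings test nothing, and P0 as the day after E18.5 adds no epithelial or mesenchymal library. No value came from leaving out erythroid cells, for which too few markers were measured, nor for mesenchymal cells of the cultures with at least 1500 genes or without the highest 20% of doublet scores. Depth limits the epithelial fits after E16.5, where libraries hold few such cells.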

Other observations

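The processed pseudogene share and the ribosomal precursor levels were examined only after the results were seen; the gene lists below were fixed beforehand.

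Some genes of cholesterol synthesis and of glycolysis and hypoxia fell with day in thymic epithelial-like cells from E13.5 to E17.5. Both lists passed with the preset correlation only. Of 17 cholesterol synthesis genes 9 fell, or 10 adjusted over the list alone, among them the demethylation enzyme gene Msmo1 (-0.51 ± 0.08 log2 per day) and Hmgcs1 (-0.39 ± 0.09), which acts early in the mevalonate pathway; camera gave adjusted p = 0.000258 with the preset correlation and adjusted p = 0.127 with an estimated correlation. Of 21 glycolysis and hypoxia genes 12 fell and 1 rose, also adjusted over the list alone, with the glycolytic enzyme genes Pkm (-0.48 ± 0.06) and Ldha (-0.42 ± 0.06) lower and the vasoactive peptide gene Adm (0.84 ± 0.14) higher; camera gave adjusted p = 0.000353 with the preset correlation and adjusted p = 0.366 with an estimated correlation. Aire rose by 1.11 ± 0.28 per day, but it stood at 0.818 ± 0.548 CPM at E13.5, 42.3 ± 12.4 at E15.5 and 12 ± 10.5 at E16.5, with 0 UMIs in the single E17.5 library.

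In T-lineage-like cells 5 of 9 Notch pathway genes fell with day, also adjusted over the list alone, including the feedback gene Nrarp (-0.82 ± 0.08 log2 per day) and the glycosyltransferase gene Lfng (-0.46 ± 0.05); camera gave adjusted p = 0.00207 with the preset correlation and adjusted p = 0.224 with an estimated correlation. In the organ cultures 2 of 10 Notch genes were higher and 1 lower with retinoic acid, or 5 and 1 adjusted over the list alone, with Heyl at 1.71 ± 0.32, Nrarp at 0.75 ± 0.16 and Lfng at -1.03 ± 0.26, the latter calls lost on leaving out any of 4 and 5 of the 6 libraries; camera gave adjusted p = 0.00951 with the preset correlation and adjusted p = 0.136 with an estimated correlation. Of 6 gamma-delta genes 3 fell and 2 rose with day, also adjusted over the list alone, with the scavenger receptor gene Cd163l1 (-0.76 ± 0.05) and the co-stimulatory gene Icos (-0.33 ± 0.04) lower and Blk (0.36 ± 0.11) and Sox13 (0.18 ± 0.06) higher; camera gave adjusted p = 0.0420 with the preset correlation and adjusted p = 0.224 with an estimated correlation. The slopes of Blk and Sox13 were negative with the first rule for naming classes. The call of Sox13 was also lost on leaving out any E13.5 library, E14.5 replicate 1 or either E18.5 library. Retinoic acid genes of epithelial cells were lower at E13.5 than at E12.5 in 4 of 13 cases, or 6 adjusted over the list alone, with Crabp1 at -2.92 ± 0.62, not called without E12.5 replicate 2; camera gave adjusted p = 0.00446 with the preset correlation and adjusted p = 0.186 with an estimated correlation.

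Transcripts of 82 processed pseudogenes, retrotransposed gene copies that share reads with their parents, made up 0.0556% and 0.0405% of UMIs in the knockout libraries and 0.134%, 0.187% and 0.147% in the wild-type libraries at E16.5. Within T-lineage-like cells the shares were 0.0512 ± 0.0130% (n = 2) and 0.160 ± 0.0294% (n = 3), and within epithelial-like cells 0.0335 ± 0.00341% and 0.0939 ± 0.0104%. Rps19-ps3 stood at 35.0 ± 5.48 CPM over all cells of the knockout and 553 ± 228 in the wild type. Over all cells the share was 0.108 ± 0.0233% at E13.5 and 0.0977 ± 0.0142% at E12.5, and 0.0678 ± 0.0115% with retinoic acid and 0.0657 ± 0.0200% in controls, so it overlapped between the groups of these comparisons. Some days overlapped and others did not, such as E14.5 at 0.0664 ± 0.00673% (n = 2) and E18.5 at 0.172 ± 0.00181% (n = 2), and the slopes were not fitted with this share as a covariate. The labels name no batch that parts these libraries. Rn45s over all cells averaged 165 ± 16 CPM at E13.5, 1150 ± 213 at E14.5 and 382 ± 110 at E16.5, 1274 ± 498 in the knockout, 1952 ± 414 in control and 3957 ± 1930 in retinoic acid cultures.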
